A study of Mus musculus and Oryctolagus cuniculus and Sus scrofa with 20 samples.

How the data were processed

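The study holds 20 small RNA libraries, each from total RNA made into a library by an Illumina small RNA protocol and sequenced on a HiSeq 2000, per the labels' protocols. Spermatocytes and round spermatids came from mice of day 9, 13 and 25, and the SSCs of the knockout experiment from a mouse of day 15 carrying a green fluorescent transgene, grown on mouse embryonic fibroblast feeder cells, per the labels' protocols. Knockout lines are single colonies picked after transfection of nuclease plasmids. Rabbit RNA was mixed with an exogenous spike-in, per the labels. Every library is its own group, assigned from its title.

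The authors deposited, for each library, a list of distinct read sequences with the count of reads of that sequence; these counts are not normalised. Sequences run from 17 to 41 nt (to 51 nt in pig), so reads had been trimmed and shorter ones removed, by steps not given in the sources used here. Reads that hold the end of the 5' adapter are still in the files, 0.0290% (rat) to 0.717% (pig) of reads, and were not taken out. The submitters' processing notes name Bowtie and the mouse, rabbit, rat and pig builds GRCm38, OryCun2.0, Rnor_6.0 and Sscrofa10.2, without roles. Reads that do not map to a genome are still in the files, so the lists were used as sequences. They hold 99077 (CRISPR) to 3713036 (pachytene) distinct sequences.

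A read of 18 to 26 nt was assigned to a miRNA if its first 18 nt equalled those of the mature miRNA. The 189 mature mouse sequences were written from knowledge of the field before the data were examined and joined into 184 entries where prefixes are shared; 188 lie in full within a miRNA hairpin of GENCODE vM21 (GRCm38), and 1 (miR-660-5p) lies in none. Reads counted this way, which may carry other 3' bases, were 86.8% (pachytene) to 101% (mature sperm) of the reads that lie exactly within any mouse hairpin in the mouse stage libraries, and up to 116% in rabbit. Entries for miR-465a, b and c and for miR-883a and b differ by few bases, so reads with errors may be split among them. Levels are reads per 1000000 miRNA reads. Coordinates are those of GENCODE vM21; they are not taken from the deposited files. Rabbit, pig and rat libraries were matched to the same mouse sequences.

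The main designs, the 13 lists of miRNAs, the 8 tRNA prefixes, the rule for naming miRNAs and most alternatives were fixed before the data were examined. Named are miR-741 in the knockout comparison; the family as a group with its most abundant members; the 5 most abundant miRNAs of a library where levels are compared; the 5 largest rises and falls among miRNAs with at least 100 reads in 1 of the libraries compared (in the knockouts ranked by the smaller of the 2 changes); and in rabbit the 10 highest and 10 lowest rho, ties ranked by the log2 difference between day 180 and day 10. Other named miRNAs belong to a fixed list or were chosen after their values were seen.

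With 1 library per group, differences between 2 libraries have no test; tests were run only for trends over the rabbit ages and, as an alternative, with edgeR for both knockout lines as 1 group. Between consecutive mouse stages a change is counted at 4-fold, in the knockouts at 2-fold the same way in both lines. A count of 0 was set to 3, and no fold is given where both counts are at or under 3. The intervals of log2 changes come from the exact conditional binomial. A list's median change was ranked among 10000 random lists of the same size, each member replaced by 1 of its 20 nearest non-members in mean level; this describes the libraries and is no test between conditions. miR-223 is in both the blood cell list and the list of X-linked miRNAs outside the family, and miR-20b-5p of the latter belongs to a miR-17/miR-106 paralogue cluster. The feeder or stromal list holds miR-10a, miR-10b, miR-99a and miR-100, which are also abundant in the germ cell libraries. Shared-control values come from 1000 simulations of 2 unchanged groups against the control, with negative binomial counts of dispersion 0.0381 taken from the 2 knockout lines. In rabbit, miRNAs with a mean of at least 10 reads were correlated with age over 8 libraries, with p-values over all orders of the ages; Pearson's r used log2 levels with 0.5 reads added. Nothing in the labels says whether libraries come from 1 or several animals. The rabbit p-values compare the order of these 8 libraries with all other orders, and no spread between animals or libraries of the same age enters them.

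Shares of reads by length use all reads. The ping-pong overlap counts pairs of 25 to 32 nt sequences whose first 5 to 20 nt are reverse complements, with no genome. tRNA 5' fragments are reads that begin with 1 of 8 prefixes of 18 nt.

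Alternatives were scaling by all reads, by edgeR's TMM factors or by DESeq2's size factors; matching by the full mature sequence, with a 5' start shifted by 1 nt, or with 1 mismatch; no filter on low counts; other thresholds, length windows, distinct sequences, sequences with at least 2 reads, overlap pairs weighted by reads; and leaving out each rabbit age. Chosen after seeing the data were counts per mouse hairpin arm, totals without miR-741, rabbit ages 10 to 90, the rabbit trend without the miR-506 family, the ping-pong score against 9 and 11 nt, the rRNA prefixes, the counts of 3' ends of miR-465a-5p, and the single differences used to summarise the length, tRNA and family results (pachytene minus zygotene, mature sperm minus round spermatid, and pre-leptotene to pachytene).

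The steps were tested on simulated data, counts except for the lists, which used simulated log2 changes. In the rabbit trend, with 40 of 141 miRNAs changed over the age range and the total unmoved, 8.6% were recovered at 2-fold, 86.8% at 4-fold and 99.5% at 16-fold, and 0.25% to 1.39% of unchanged miRNAs were called. When the changed miRNAs were allowed to move the total, 16.0% of unchanged miRNAs were called at 4-fold and 74.7% at 16-fold, so rabbit changes are changes of share. In the knockout step, with 40 of 119 changed, the 2-fold rule recovered 34.1% at 2-fold and 92.5% at 4-fold, and named 0.51% and 3.99% of unchanged miRNAs. Lists moved by 2 on the log2 scale were placed outside the random lists in 95.0% of runs, and unmoved ones in 5.0%. edgeR recovered 7 of 20 miRNAs at 2-fold and 20 of 20 at 4-fold and called 1 of 79 unchanged. Planted 10-nt pairs raised the ping-pong ratio from 1.00 to 7.54. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 were used.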

Results

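Small RNA was sequenced from 20 libraries, 1 per group, from purified mouse male germ cells, rabbit testis at 8 ages, adult pig and rat testis, and cultured mouse spermatogonial stem cells (SSCs) with and without miR-741. The mouse series runs from SSCs through pre-leptotene, leptotene, zygotene and pachytene spermatocytes to round spermatids and mature sperm. Leptotene, zygotene and pachytene are successive stages of the first meiotic prophase. The 7 libraries of that series hold 20302560 (SSC), 13169831 (pre-leptotene), 12247017 (leptotene), 15317355 (zygotene), 22785285 (pachytene), 23552284 (round spermatid) and 25908109 (mature sperm) reads. Rabbit libraries hold 7400969 (day 70) to 13218352 (day 110) reads, the pig library 13045778 and the rat library 6030281. The control SSC library holds 1449449 reads, the miR-741 knockout line made with a TALEN nuclease 843664 and the line made with CRISPR 597732. Reads assigned to listed miRNAs number 371910 in pachytene spermatocytes, 642514 in round spermatids and 3625578 to 6012450 in the other mouse stages; the 3 knockout comparison libraries have 461257, 261105 and 197569. No group has a replicate, so no difference between groups has a replicate check, and a comparison of 2 libraries compares those libraries. The intervals given are 95% exact Poisson or Clopper-Pearson intervals, and without molecular identifiers they cover counting error only.

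The first comparison follows the X-linked miR-506 family, the subject of the series, through mouse spermatogenesis. The family made up 45.8% of miRNA reads in cultured SSCs, 75.2% in pre-leptotene, 75.6% in leptotene, 61.0% in zygotene and 38.1% in pachytene spermatocytes, 23.2% in round spermatids and 7.83% in mature sperm; the widest counting interval, in pachytene, ran from 37.9% to 38.2%. Its most abundant member was miR-741-3p, at 14.2% of miRNA reads in SSCs, 38.9% in pre-leptotene, 40.8% in leptotene, 30.2% in zygotene and 16.5% in pachytene spermatocytes, 10.7% in round spermatids and 2.40% in mature sperm. miR-871-3p came next, with 20.4% in pre-leptotene and 0.429% in mature sperm. From SSC to pre-leptotene miR-741-3p rose by 1.46 and miR-871-3p by 1.11 on the log2 scale, while miR-880-3p fell by 2.65 and miR-881-3p fell by 2.57, so that 7 of the 27 family members measured were higher and 20 lower.

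The Mir741 hairpin lies on chromosome X at 66796805 to 66796875, minus strand, in GENCODE vM21 on GRCm38. It overlaps no other annotated gene and falls between the protein-coding genes Slitrk2 (66649318 to 66661393) and Gm1140 (67682900 to 67693562). That interval holds 18 of the 21 matched family hairpins, from 66776757 to 66839125, a span of 62.4 kb.

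**Figure D1:**
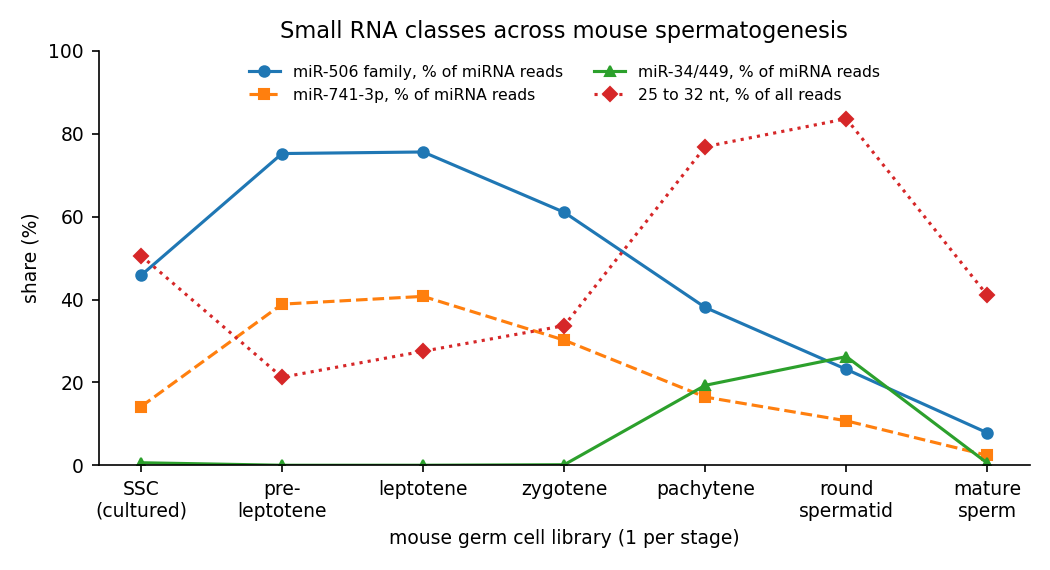
Share of miRNA reads (%) taken by the miR-506 family, miR-741-3p and miR-34/miR-449, and share of all reads (%) of 25 to 32 nt, in the 7 mouse libraries, 1 per stage; counting intervals are smaller than the symbols. The family's share of miRNA reads peaks at 75.6% in leptotene spermatocytes (scaled by all reads its log2 change from pre-leptotene was -0.23), and the 25 to 32 nt share at 83.6% in round spermatids.

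Between SSCs and pre-leptotene spermatocytes, of 160 miRNAs with at least 100 reads in 1 of the libraries, 7 were at least 4-fold higher and 73 at least 4-fold lower. The SSCs were cultured and the spermatocytes came from mice of day 9. Culture therefore cannot be told apart from stage at this step, for the miR-506 family too. The largest falls were miR-221-3p (log2 change -9.36), miR-222-3p (-8.42), miR-449c-5p (-8.11), miR-291a-3p (-7.33) and miR-205-5p (-6.91). The largest rises were miR-202-5p (6.63), miR-547-3p (4.22), miR-99a-5p (2.79), miR-15b-5p (2.71) and miR-342-3p (2.14). miR-202-5p is listed as a Sertoli or gonadal marker, and whether its rise comes from germ cells or other cells was not tested. All 7 measured members of the pluripotency-associated miR-290/miR-302 clusters were at least 4-fold lower, with a median 4.09 below that of all miRNAs (percentile 0.06 of 10000 lists of the same size and level), as were all 4 miR-34/miR-449 members (percentile 0.03) and all 9 of the imprinted Dlk1-Dio3 cluster (percentile 6.48). Scaling decides much of the count: the median of all measured miRNAs was -1.66, and with TMM factors, which move that median to 0.01, 24 were higher and 39 lower; scaled by all reads, 12 were higher and 54 lower.

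Pre-leptotene and leptotene libraries, both from day 9, were nearly alike: none of 138 miRNAs differed 4-fold, with a Spearman's rho of 0.994 across miRNAs, which are not independent replicates. The largest differences were a log2 rise of 1.70 for miR-293-3p, with miR-378a-3p (1.37), miR-292a-5p (1.18), miR-295-3p (0.98) and miR-381-3p (0.75) behind it, and falls of miR-410-3p (-1.58), miR-322-5p (-0.60), miR-363-3p (-0.59), miR-328-3p (-0.59) and miR-880-3p (-0.54).

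In zygotene spermatocytes, from day 13, 16 of 151 miRNAs were at least 4-fold higher than in leptotene and none lower. The leptotene cells came from day 9, so age of the mice cannot be told apart from stage at this step. miR-202-5p rose most (log2 4.46, 728 against 14870 reads), followed by miR-204-5p (4.40), miR-202-3p (4.29), miR-291a-3p (3.68) and miR-429-3p (3.32). The miR-202 entries form the Sertoli or gonadal list, and whether their rise comes from germ cells or other cells was not tested. The largest declines were small: miR-742-3p (-1.10), miR-423-5p (-0.48), miR-151-3p (-0.44), miR-741-3p (-0.43) and miR-141-3p (-0.38). X-linked miRNAs outside the miR-506 family had a median 0.87 above that of all miRNAs (percentile 99.5), and the 7 let-7 entries, a differentiation-linked family, 0.55 above (percentile 99.6). The 11 feeder or stromal markers lay 0.18 above (percentile 98.5), and the miR-506 family 0.62 below (percentile 0.05). With TMM or DESeq2 factors 9 miRNAs passed in place of 16; the median of all miRNAs was 0.86, and 0.15 with TMM factors.

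From zygotene to pachytene spermatocytes the miR-34/miR-449 family, which shares a seed and is known to be abundant in late meiotic and haploid male germ cells, had 3 of 4 measured members at least 4-fold higher, with a median 7.97 above that of all miRNAs (percentile 100): miR-449a-5p rose by 8.28, miR-449c-5p by 7.91 and miR-34c-5p by 7.15 on the log2 scale, while miR-34a-5p was at 0.65. miR-34c-5p reached 18.6% of miRNA reads. Next were miR-375-3p (5.86) and miR-425-5p (5.47), and the 9 members of the proliferation-linked miR-17/miR-106 clusters were all higher, with a median 2.13 above that of all miRNAs (percentile 99.96). The largest falls were miR-503-5p (-4.75, 95% interval -10.06 to -2.26, 1 read in pachytene), miR-351-5p (-3.82), miR-20b-5p (-3.54), let-7e-5p (-3.51) and miR-290a-5p (-3.41). X-linked miRNAs outside the miR-506 family were lower in 11 of 12 cases, with a median 1.41 below that of all miRNAs (percentile 0.17). All 11 feeder or stromal markers were lower too, with a median 0.96 below (percentile 0.03), among them miR-10b-5p (-2.40) and miR-99a-5p (-2.11). The miR-506 family had a median 0.04 below that of all miRNAs (percentile 6.41), and its sum fell by 0.68 per miRNA reads, by 0.54 with TMM factors and by 4.82 per all reads. Of 153 miRNAs, 10 were at least 4-fold higher and 20 lower when scaled by miRNA reads; scaled by all reads 3 were higher and 143 lower, and the median went from -0.44 to -4.59, since the miRNA share of reads was 28.8% in zygotene and 1.63% in pachytene. miR-34c-5p rose under every scaling, by 3.01 to 7.43. The zygotene cells came from mice of day 13 and the pachytene cells from mice of day 25, so age cannot be told apart from stage here.

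Between pachytene spermatocytes and round spermatids, both from day 25, 5 of 99 miRNAs were at least 4-fold higher and 7 lower. miR-497a-5p (log2 3.93) and miR-195a-5p (3.50), which come from 1 cluster, rose most, with miR-146a-5p (3.24), miR-124-3p (2.58) and miR-375-3p (2.21). miR-449c-5p fell most (-8.82; 525 against 2 reads, 95% interval -11.87 to -6.96), followed by miR-106b-5p (-3.46), miR-320-3p (-3.40), miR-145a-5p (-2.93) and miR-17-5p (-2.68). miR-34c-5p was the most abundant miRNA in round spermatids, at 25.7% of miRNA reads, followed by miR-191-5p at 19.2%. The miR-506 family fell by 0.72 per miRNA reads, but by all reads the change was 0.02 and with TMM factors 0.04. The split was 7 higher and 4 lower with TMM factors and 6 higher and 4 lower by all reads, and the median moved from -0.41 to 0.34 with TMM factors.

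Mature sperm differed from round spermatids in 65 of 137 miRNAs, 39 at least 4-fold higher and 26 lower. With full-sequence matching 49 were higher and 13 lower, and the median of all miRNAs was 1.12 in place of 0.29. All 3 measured miR-34/miR-449 members were lower: miR-34c-5p fell by 5.67 and miR-449a-5p fell by 5.47, miR-34b-5p fell by 4.84, and miR-497a-5p (-6.63) and miR-15a-5p (-4.92) fell with them. miR-191-5p was the most abundant miRNA, at 33.7% of miRNA reads, followed by miR-10b-5p at 9.67% and miR-10a-5p at 8.82%. The 5 largest rises, whose order is open because counts of 0 were set to 3, were miR-222-3p (9.08, 95% interval 6.60 to 14.38, 1 read in round spermatids), miR-429-3p (8.95, 1 read), miR-150-5p (0 against 7325 reads, at least 432.7-fold), miR-200a-3p (8.07) and miR-451a (0 against 3565 reads, at least 210.6-fold). Of 8 epithelial markers 6 were at least 4-fold higher, led by miR-200a-3p at 25788 reads, and 1, miR-375-3p, lower. All 5 blood cell markers were higher, led by miR-486a-5p at 32683 reads. Of 11 feeder or stromal markers 9 were higher, and that list took 27.5% of miRNA reads against 3.59% in round spermatids. The medians of these lists lay at percentiles 100, 99.93 and 99.94, with counts of 0 set to 3. X-linked miRNAs outside the miR-506 family were higher in 10 of 10 cases (percentile 99.4), 6 of them 4-fold, let-7 in 5 of 7 (percentile 98.0), and the 8 miR-17/miR-106 members were all lower (percentile 0.26). The miR-506 family fell by 1.56 per miRNA reads and rose by 0.79 per all reads. Scaled by all reads, 85 miRNAs were higher and 5 lower, and the median moved from 0.29 to 2.64; miR-34c-5p fell under every scaling, by 3.31 to 6.07.

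Read lengths separate miRNA-sized reads of 20 to 24 nt from the 25 to 32 nt reads typical of piRNAs, the small RNAs that guide PIWI proteins in the germline. The longer window also takes in tRNA 5' fragments, so it does not hold piRNAs alone. Such fragments of 25 to 34 nt numbered 4751752 reads in mature sperm and 162025 in round spermatids. The 25 to 32 nt share was 50.6% in SSCs, 21.2% in pre-leptotene, 27.5% in leptotene, 33.7% in zygotene and 76.9% in pachytene spermatocytes, 83.6% in round spermatids and 40.98% in mature sperm. The share of these reads that start with T, as most primary piRNAs do, was 37.7% in pre-leptotene, 87.7% in pachytene, 88.9% in round spermatids and 23.9% in mature sperm. Pig testis had 25.8% of reads at 25 to 32 nt and rat testis 83.7%, with 51.3% and 88.2% starting with T. The 3 knockout comparison libraries had 32.1% (control), 34.6% (TALEN) and 27.5% (CRISPR). Counted over distinct sequences the share was 72.8% in SSCs, 63.6% in zygotene and 71.3% in pachytene spermatocytes, so that SSCs lay above pachytene, the reverse of the order by reads.

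Ping-pong piRNA pairs overlap by 10 nt at their 5' ends. The z-score fixed for this overlap lay between -0.32 and -0.30 in every library because short chance overlaps outnumber all others, so it does not separate the libraries. A score chosen after seeing this, pairs above chance at 10 nt over those at 9 and 11 nt, was highest in zygotene spermatocytes (3.64) over distinct sequences and was 1.94 in pachytene spermatocytes, 2.38 in round spermatids, 2.28 in mature sperm and 1.79 in rabbit testis at day 110, the lowest. Weighted by reads the order changed: round spermatids had the highest value (33.7), ahead of rabbit testis at day 180 (20.5), day 110 (18.8) and pachytene spermatocytes (11.6), zygotene spermatocytes had 9.26, and mature sperm had -1.46. Over distinct sequences the excess over chance at 11 nt was as large as that at 10 nt in several libraries, such as pachytene spermatocytes (ratios of 2.52 and 2.498).

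tRNA 5' fragments, a class known from sperm, took 18.9% of reads in mature sperm, against 0.740% in round spermatids, 0.386% in pachytene spermatocytes and 9.27% in SSCs. Those with the tRNA-Gly-GCC/CCC prefix made up most of the sperm signal, at 14.8% of reads, with 0.285% for the other tRNA-Gly prefix and 1.73% for tRNA-Glu-CTC fragments. The share was 7.33% in rabbit testis at day 10 and 3.94% at day 180, 8.03% in pig and 0.758% in rat testis, and 8.60%, 6.85% and 7.57% in control, TALEN and CRISPR SSCs.

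The rabbit series asks how testicular small RNAs change with age, from day 10 to day 180, with 1 library per age. Per 1000000 miRNA reads, 29 of 141 miRNAs rose and 20 fell with age (Spearman's rho, exact two-sided permutation test, Benjamini-Hochberg adjusted over 141 miRNAs). Of the rises 5 are entries of the miR-506 family, and without the family 24 rose and 20 fell. The family's reads numbered 1722 at day 10 and 1049 at day 180, while miRNA reads went from 4169590 to 851481, so its rises are of share only. miR-34c-5p and miR-15a-5p rose at every step (rho 1, exact p = 4.96e-05, the smallest that rho can give over 8 ages, adjusted p = 0.0035), and miR-34c-5p went from 72.2 to 84311 per 1000000, a log2 difference of 10.19 and a Pearson's r of 0.885 (exact p = 2.48e-05). miR-449a-5p (8.51), miR-200a-3p (4.89) and miR-191-5p (2.07) followed with rho 0.976, then miR-1a-3p (3.91) and miR-133a-3p (3.41) with 0.952 and miR-9-5p (6.45), miR-200c-3p (5.99) and miR-203-3p (3.57) with 0.929. The steepest falls by rho were miR-214-3p (-2.46), miR-199a-5p (-2.20), miR-181b-5p (-1.40) and let-7d-5p (-1.29) at -0.976, miR-342-3p (-1.93) at -0.952, miR-199a-3p (-2.20), miR-99a-5p (-1.04) and let-7e-5p (-0.91) at -0.929, and miR-410-3p (-3.89) and miR-652-3p (-1.93) at -0.905.

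The libraries of days 110 and 180 stood apart from the younger ages: across miRNAs, which are not independent replicates, they had rho 0.99 with each other and 0.83 to 0.94 with each earlier age, against 0.94 to 0.99 among the earlier ages. By list, 3 of 4 tested miR-34/miR-449 members and 5 of 6 epithelial markers rose, and 4 of 11 feeder or stromal markers and 4 of 7 Dlk1-Dio3 members fell; adjusted over the list alone the counts were 3, 5, 4 and 5. Both muscle miRNAs of the 3 endothelial and muscle markers rose, as did 1 of 2 liver or neural markers, miR-9-5p, and the 1 miR-290/miR-302 entry tested. Of let-7, 2 of 7 fell, and of 16 other X-linked miRNAs 1 rose and 3 fell; adjusted over the list alone these counts were the same. Of the 9 miR-17/miR-106 members 1 fell, and 0 when adjusted over the list alone. None of the 5 blood cell markers and not the Sertoli or gonadal marker miR-202-5p passed, adjusted over the list alone or over all. The sum of the feeder or stromal markers went from 55.2% of miRNA reads at day 10 to 39.3% at day 180. Its rho was -0.76 (exact permutation p = 0.0368, adjusted p = 0.0796 over the sums of 13 lists). Without day 10, 30 or 180 alone rho was -0.64 (exact permutation p = 0.139). Per all reads rho was -1 (adjusted exact permutation p = 0.000645), and with TMM factors -0.93 (adjusted exact permutation p = 0.00725). The members did not move together between days 10 and 180. miR-99a-5p went from 31.0% to 15.1% and miR-10b-5p from 11.2% to 7.25%. miR-143-3p went the other way, from 3.75% to 11.4%, and miR-145a-5p, miR-152-3p and miR-10a-5p were also higher at day 180. Of 15 miR-506 family entries 5 rose, adjusted over the list alone or over all, and their sum had rho 0.74 per miRNA reads and -0.74 per all reads (exact permutation p = 0.0458 for both, adjusted p = 0.0851 and 0.0596 over the 13 lists). With TMM or DESeq2 factors rho was 0.62 (exact permutation p = 0.115), and without day 30, 60, 70, 90, 110 or 180 alone the exact permutation p was 0.0663 to 0.167. These are reads of mouse sequence, described with the other species. Other sums depended on the scaling too. Per miRNA reads rho was -0.17 for let-7, 0.43 for the blood cell markers, -0.45 for miR-17/miR-106, -0.43 for the other X-linked miRNAs and 0.69 for the endothelial and muscle markers, and none passed (adjusted exact permutation p 0.113 to 0.762). Per all reads these were -0.98, -0.98, -0.90, -0.86 and -0.76, of which the first 4 passed (adjusted exact permutation p 0.00103 to 0.0174) and the last did not (0.0531). The miR-290/miR-302 sum had rho 0.88 per miRNA reads (adjusted exact permutation p = 0.0188) and 0.26 per all reads (0.581). The liver or neural sum had 0.93 (adjusted exact permutation p = 0.00967) and 0.12 (0.793). Both passed with TMM factors (0.0119 and 0.00725).

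The rabbit counts depended on the scaling and on which ages entered. Scaled by all reads 5 rose and 62 fell, with TMM factors 14 and 24, and with DESeq2 factors 20 and 25; miR-34c-5p, miR-449a-5p, miR-141-3p, miR-200a-3p and miR-200c-3p rose in each. Without days 10 and 180 the counts were 5 and 3 and all 49 called miRNAs kept their sign, over ages 10 to 90 they were 0 and 0, without day 110 alone 7 and 5, without day 180 alone 8 and 5, without day 10 alone 12 and 10, and without day 30 alone 12 and 10.

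The 25 to 32 nt share of rabbit reads was 22.9%, 24.6%, 23.8%, 24.6%, 30.7% and 39.0% at days 10, 30, 60, 70, 80 and 90, and 71.1% and 76.8% at days 110 and 180. Its correlation with age was rho 0.929 (exact permutation p = 0.00223) and r 0.874 (exact permutation p = 0.000149). Without days 10 and 180 rho was 0.829 and r 0.797 (exact permutation p = 0.0583 for both), and over ages 10 to 90 rho was 0.829 (exact permutation p = 0.0583) and r 0.728 (exact permutation p = 0.0806). The relation therefore did not pass without days 10 and 180, and 6 ages also leave fewer orders to permute, with a lowest p of 0.00278. Without any 1 age rho stayed at 0.893 or above (exact permutation p at most 0.0123). Over distinct sequences the share was 72.6% at day 10 and 75.1% to 78.3% at the later ages (rho 0.857, exact permutation p = 0.0107). The miRNA share of reads went from 55.2% at day 10 to 8.86% at day 180. tRNA 5' fragments of 25 to 34 nt, whose lengths overlap the 25 to 32 nt window, numbered 526680 reads at day 10 and 367366 at day 180.

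**Figure D2:**
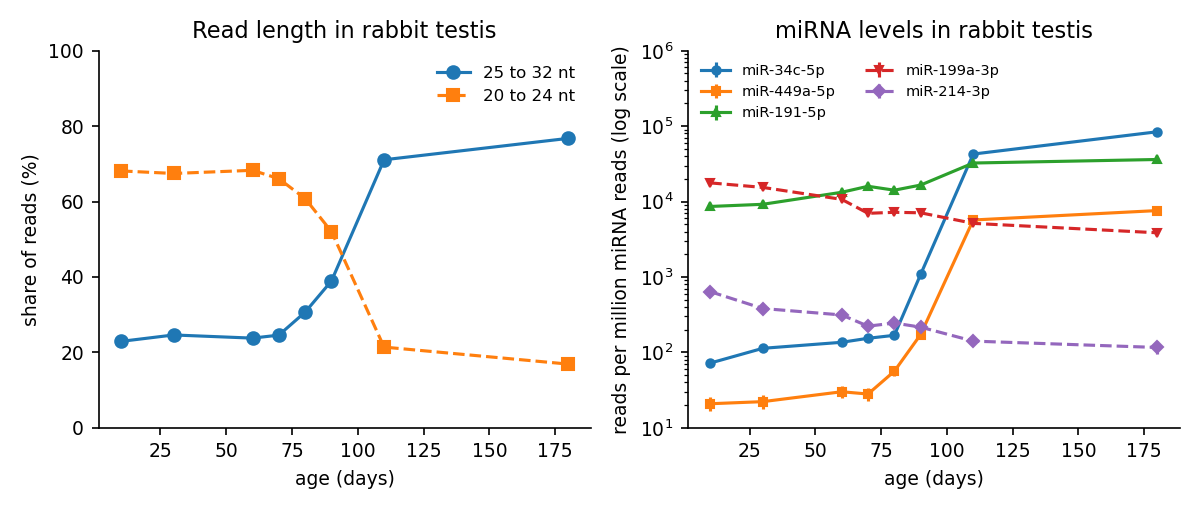
Left, share of reads (%) of 25 to 32 nt and of 20 to 24 nt against age (days) in 8 rabbit testis libraries, 1 per age. Right, reads per 1000000 miRNA reads (log scale) of 5 miRNAs with 95% Poisson intervals; miR-34c-5p goes from 72.2 at day 10 to 84311 at day 180, and the 25 to 32 nt share from 39.0% at day 90 to 71.1% at day 110.

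Adult testes of rabbit (day 180), pig and rat were compared for the miR-506 family and for their leading miRNAs, all matched to mouse mature sequences, so that orthologs with another 5' sequence are not seen. In rat testis miR-34c-5p led, at 34.2% of miRNA reads, ahead of miR-143-3p (8.17%), miR-99a-5p (7.64%), miR-100-5p (4.21%) and miR-10b-5p (3.06%). In pig testis miR-99a-5p (35.1%) and miR-10b-5p (17.8%) led, followed by miR-143-3p (5.39%), miR-21a-5p (5.15%) and let-7a/c-5p (3.48%). Rabbit testis had miR-99a-5p (15.1%), miR-143-3p (11.4%), miR-34c-5p (8.43%), miR-26a-5p (7.29%) and miR-10b-5p (7.25%). The miR-34/miR-449 list thus took 37.3% in rat, 9.26% in rabbit and 0.989% in pig. The blood cell markers took 0.329%, 0.0709% and 0.190% in the same order. The rat value rests on 1 marker, miR-486a-5p, which alone took 0.2998% there. miR-451a went the other way, at 0.0034% in rat, 0.0417% in rabbit and 0.0854% in pig, so the list does not order the testes by blood content.

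Rat testis had 5769 reads of family sequence, 13254 per 1000000 miRNA reads. Of 32 family entries, 7 had at least 10 reads: miR-471-5p (5415 per 1000000, 95% interval 5198 to 5638), miR-883b-3p (2245), miR-471-3p (1925), miR-743b-5p (1326), miR-463-5p (1190.0), miR-883a-5p (797) and miR-742-5p (317). The mouse form of miR-741-3p had 2 reads in rat, and miR-465a-5p 0, which at a limit of 3 reads allows up to 6.89 per 1000000. With 1 mismatch outside the first 8 nt, 11 entries had at least 10 reads. Mouse-sequence family reads were also present in rabbit, 1049 to 2007 per library or 109 to 271 per 1000000 reads, and in pig, 422 reads or 32.3 per 1000000 reads. Across members their counts followed those of the mouse SSC library, with rho 0.923 to 0.966 in the rabbit libraries, 0.853 in pig and 0.132 in rat; members are not independent replicates. In the rabbit libraries together 59.6% of 1000 abundant piRNA-sized sequences of mouse SSCs had a read as well, with 33274 reads, 4.87% of their reads in mouse SSCs, against 0.532% for the family. These 1000 were the most abundant that start with T, have no tRNA prefix and have under 10 reads in the rat library. Single rabbit libraries held 20.1% (day 180) to 27.0% (days 70 and 110) of them.

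The last comparison asks what losing miR-741 does to other miRNAs in SSCs grown on feeder cells. miR-741-3p had 80096 reads in the control, 17.4% of miRNA reads, 3 in the TALEN line and 5 in the CRISPR line: log2 changes of -13.88 (95% interval -16.16 to -12.34) and -12.74 (-14.37 to -11.52). Of 119 miRNAs with at least 100 reads, 14 were at least 2-fold higher in both lines and 9, miR-741-3p among them, lower in both. Within the family, miR-465a-5p rose most, by 2.84 in the TALEN and 2.44 in the CRISPR line, to 8.82% and 6.68% of miRNA reads, and miR-463-3p (2.76 and 2.09) and miR-883a-5p (1.34 and 1.45) rose too, while the abundant miR-871-3p (-0.33 and -0.17) and miR-470-5p (-0.05 and -0.07) stayed within 2-fold. Of 24 family members measured, 18 were above 0 in the TALEN and 20 in the CRISPR line, with medians 0.32 and 0.34 above that of all miRNAs (percentiles 93.7 and 95.3). The other large rises were miR-378a-3p (2.41 and 2.29), miR-30e-5p (2.25 and 2.07) and miR-497a-5p (1.77 and 1.51).

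Besides miR-741-3p, the largest falls were miR-351-5p (-1.96 and -1.48), miR-181a-5p (-2.11 and -1.39), miR-199a-3p (-1.66 and -1.32) and miR-434-3p (-1.81 and -1.27). The feeder or stromal markers had medians 1.43 and 1.05 below that of all miRNAs (percentile 0.0 in both lines), although miR-143-3p of that list rose by 1.71 and 1.31. All 7 let-7 entries lay below 0 in both lines (percentiles 4.72 and 3.89), and so did all 6 Dlk1-Dio3 members (percentiles 3.0 and 3.58). Of 9 X-linked miRNAs outside the family 7 and 8 lay below 0 (percentiles 9.14 and 1.41), and of the miR-17/miR-106 clusters 6 of 8 lay above 0 in the TALEN and 5 of 7 in the CRISPR line (percentiles 99.7 and 99.3). Of the list miR-106b-5p and miR-19a-3p were at least 2-fold higher in both lines, while miR-25-3p (-0.53 and -0.37) and miR-92a-3p (-0.31 and -0.08) lay below 0.

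Between the 2 knockout lines 3 of 119 miRNAs (2.52%) differed 2-fold. Both lines share the 1 control, which cannot be split. Unchanged groups simulated against it gave a mean of 0.163 miRNAs higher and 0.1 lower in both lines (at most 3 and 2), and independent lists would share 2.71 and 1.44. Across miRNAs without miR-741-3p the log2 changes correlated with r 0.94, against 0.49 in the simulations, with 89.0% of the same sign against 66.2%; the covariance was 0.769 against 0.0846, a difference of 0.684. The spread of the simulations comes from the 2 knockout lines, so it leaves out variation between control cultures. These values therefore do not separate a change in the knockout lines from a difference of the 1 control culture. Part or all of the agreement may come from the shared control. Losing miR-741 reads alone raises every other miRNA's share by 0.28. With TMM or DESeq2 factors 12 were higher and 15 lower, and with miR-741 out of every total 11 and 16. Against the other wild-type SSC library, of another strain label, 10 were higher and 19 lower, and 10 of the 23 remained: miR-465a-5p, miR-463-3p and miR-497a-5p higher, and miR-741-3p with 6 others lower. Against that library miR-883a-5p was at -0.09 in the TALEN and 0.02 in the CRISPR line, and miR-203-3p at -0.40 and -0.91. Treating both lines as 1 group, edgeR's quasi-likelihood test with 1 residual degree of freedom called 11 higher and 16 lower at adjusted p below 0.05; its spread comes from the 2 knockout lines alone, so it does not measure variation between control cultures.

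**Figure D3:**
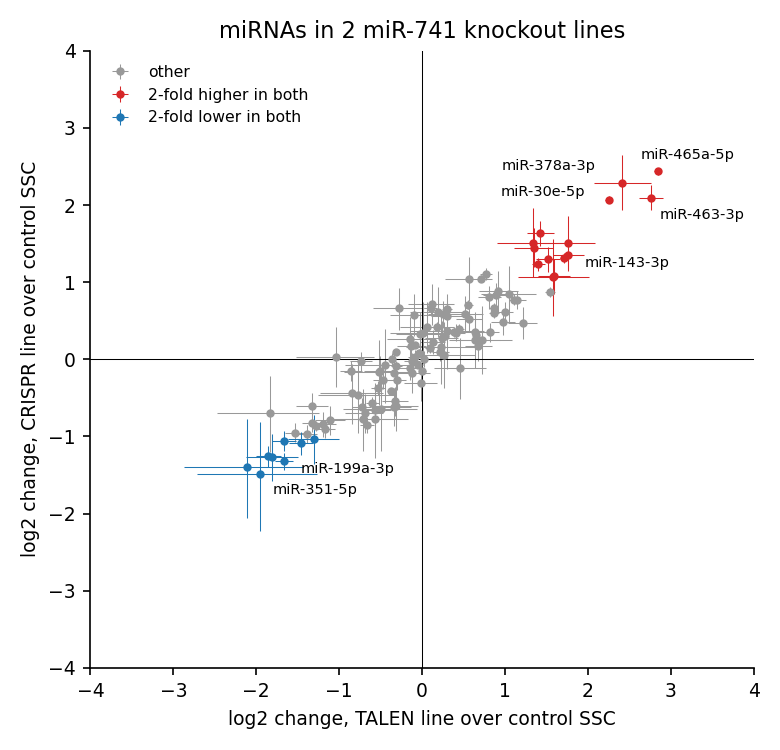
Log2 change over the control SSC library of each miRNA with at least 100 reads, TALEN line on the x axis and CRISPR line on the y axis, with 95% counting intervals; miR-741-3p (-13.88 and -12.74) lies outside the axes and is not drawn. Red, at least 2-fold higher in both lines, led by miR-465a-5p; blue, at least 2-fold lower in both.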

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

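Tests chosen only after the result was seen were the order of miRNA reads in rabbit, the count with miR-741 out of every total, the share of feeder or stromal markers lower in the knockouts, the stromal markers in mature sperm, the 3' ends of miR-465a-5p and the counts of rRNA ends and of the 5p arm of miR-741.

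Mouse-sequence reads of the miR-506 family were present in all 8 rabbit libraries and in pig, and only the mouse SSC library was compared as their source. Their order across members followed that of the mouse SSC library, with rho 0.966 for the rabbit libraries together against 0.95 for the miR-17/miR-106 clusters, a conserved group, so conservation in rabbit cannot be told apart from other causes by this order, although other lists were lower, such as 0.15 for Dlk1-Dio3; this comparison replaced the family's rho alone, which had restated the pattern. Of 1000 abundant piRNA-sized mouse SSC sequences 59.6% had a read in rabbit, fewer than the 890.6 that the family's rate would give, although their reads were 4.87% of those in mouse SSCs against 0.532% for the family; 77 of the 1000 had a read in pig. Carry-over from a mouse library is a candidate explanation for the rabbit family reads; why fewer sequences but more reads were found than at the family's rate stays open, and conserved sequences were not excluded. The rat reads differ in their order (rho 0.132), and no explanation was tested for them.

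The miRNAs changed in both knockout lines did not follow from the loss of miR-741 reads alone. That loss raises every other miRNA's share by 0.28 on the log2 scale, which alone gives no fall and no 2-fold rise. The recount therefore adds little: with miR-741 out of every total 87.0%, miR-741-3p among them, were still named. The counts were then 11 higher and 16 lower. GC content had a rho of -0.17 with the mean change across miRNAs, although the median GC share was 41.9% in those higher and 48.9% in those lower. Fewer feeder or stromal cells as the cause of the falls stays open and cannot be told apart from a change within the SSCs: 80.0% of the 10 measured markers, among them 3 of the 8 falls besides miR-741-3p, were lower in both lines, while miR-143-3p rose by 1.71 and 1.31. This share replaced the change of miR-143-3p alone, which had been picked because it rose most. Also open are a difference between the single control library and any other SSC culture, since 10 of 23 miRNAs remained against the other wild-type SSC library, and an effect of miR-741 itself, which 1 control cannot separate from it. Both knockout lines are also single colonies picked after transfection of nuclease plasmids, and effects of these steps were not tested.

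Epithelial and blood miRNAs were far higher in mature sperm than in round spermatids. The tables argue against deeper sampling of sperm miRNAs as the cause: with sperm counts thinned to 642514 reads, 90.9% of the 11 rises were still named. RNA of other tissue cells is a candidate explanation, since 81.8% of the feeder or stromal markers, which are not part of the pattern, were at least 4-fold higher too. This test replaced another, the share of epithelial or blood markers 4-fold higher, after that had been run, because the first restated the pattern; it would have pointed the same way. The feeder or stromal list holds miRNAs that germ cells also express, and uptake of RNA by sperm from the epididymis was not tested.

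A signal outside the comparisons was found in 3 places. Reads that start at the 5' end of 28S rRNA made up 14.5% of mature sperm reads, against 0.115% in round spermatids and 0.513% in control SSCs. Zygotene and pre-leptotene spermatocytes lay between, with 334296 of 15317355 reads and 188730 of 13169831 reads. Reads over 32 nt made up 28.9% of mature sperm reads and 8.41% of control SSC reads. In the other mouse stages they made up 3.96% (round spermatids) to 13.9% (zygotene). The 5p arm of miR-741 had 275 reads in control SSCs and 0 in both knockout lines.

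Of 119 miRNAs with at least 100 reads, 13 had log2 changes of opposite sign in the 2 knockout lines, and in 2 of them both 95% counting intervals left out 0: miR-10a-5p by -0.08 in the TALEN and 0.19 in the CRISPR line, and miR-21a-5p by -0.32 and 0.10. The difference between the lines was not tested.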

How the results depend on the processing

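Chosen only after the data were seen were the counts per hairpin arm, the totals without miR-741, ages 10 to 90, the trend without the miR-506 family and the ping-pong score over 9 and 11 nt. Of the alternatives run for results that answer a comparison, 128 left the result on its side of the threshold or within its allowed range, 80 moved it, 9 left it no longer past the threshold and 7 turned its direction: 6 changes of the miR-506 family between mouse stages and its trend in rabbit. Of the other values 158 stayed, 131 moved, 6 no longer passed, 11 newly passed and 22 turned; the ones that newly or no longer passed are all sums of lists in rabbit, by unadjusted p. The score of pairs above chance at 10 nt over those at 9 and 11 nt was -1.46 in mature sperm when weighted by reads. The cause of these moves was not tested except where the alternative's construction shows it.

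With hairpin arms, which count more sequences, the miRNAs that changed 4-fold numbered 282 (SSC to pre-leptotene), 3 (to leptotene), 39 (to zygotene), 98 (to pachytene), 57 (to round spermatid) and 149 (to mature sperm). The split with hairpin arms was 55 higher and 43 lower at the pachytene step, against 10 and 20 in the main count. At the round spermatid step it was 11 and 46, against 5 and 7. With no filter the changed miRNAs were 4 at the leptotene, 26 at the zygotene and 28 at the round spermatid step, the last 5 higher and 23 lower. Full-sequence matching gave 1 at the leptotene step, and 7 higher and 5 lower at the round spermatid step. TMM and DESeq2 factors gave 9 each at the zygotene step, and all reads 146 at the pachytene step.

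The family's change between stages turned with the scaling at 3 steps. From pre-leptotene to leptotene it was 0.01 per miRNA reads, -0.23 by all reads, -0.12 with TMM and -0.0783 with DESeq2 factors, 0.0041 with full-sequence matching and 0.0033 with hairpin arms. From pachytene to round spermatid, against -0.72, it was 0.0235 by all reads, 0.0372 with TMM and -0.18 with DESeq2 factors, -0.58 with full-sequence matching and -0.75 with hairpin arms. From round spermatid to mature sperm, against -1.56, it was 0.79 by all reads, -1.97 with TMM and -1.73 with DESeq2 factors, -0.62 with full-sequence matching, -1.61 with a shifted start and -1.48 with hairpin arms. From SSC to pre-leptotene, by all reads, TMM and DESeq2 factors and hairpin arms, it was 1.60, 2.39, 2.41 and 0.72. To zygotene, in the same order, it was -0.74, -1.02, -1.06 and -0.30, with -0.19 for full-sequence matching, and to pachytene -4.82, -0.54, -0.41 and -0.87, with -0.82 for full-sequence matching and -0.66 for a shifted start. Of miR-741-3p, miR-871-3p, miR-34c-5p and miR-449a-5p, 3 turned at some of these steps. From pre-leptotene to leptotene miR-741-3p had -0.17 by all reads, -0.0555 with TMM and -0.0175 with DESeq2 factors, miR-449a-5p -0.18, -0.0743 and -0.0362, and miR-34c-5p -0.13 by all reads and -0.0181 with TMM factors. miR-741-3p had 0.12 by all reads and 0.14 with TMM factors at the round spermatid step and 0.20 by all reads at the mature sperm step. From pre-leptotene to pachytene the family's change was -5.79 by all reads, -1.01 with full-sequence matching, -0.97 with a shifted start, -1.67 with TMM, -1.55 with DESeq2 factors and -1.17 with hairpin arms.

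In the knockouts, higher miRNAs numbered 23 with no filter, 26 at 1.5-fold and 4 at 4-fold. Lower ones numbered 15 with TMM and 15 with DESeq2 factors, 19 against the other wild-type SSC library, 22 at 1.5-fold, 1 at 4-fold, 16 without miR-741 in the totals, 18 with hairpin arms and 16 with edgeR. Of the 23 miRNAs named, miR-741-3p, miR-465a-5p and miR-463-3p were named in all 11 settings compared.

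In rabbit, 5 rose by all reads, 14 with TMM factors, 16 by Pearson's r with log2 age, 0 over ages 10 to 90 and 5 without days 10 and 180; 62 fell by all reads, 11 by Pearson's r, 0 over ages 10 to 90 and 3 without days 10 and 180. Leaving out 1 age gave 7 to 25 rises and 5 to 17 falls, with 12 and 10 without day 10, 12 and 10 without day 30, 7 and 5 without day 110, and 8 and 5 without day 180. Pearson's r with age itself called 66, rises and falls together, and without the miR-506 family 24 rose and 20 fell. Fewer ages leave fewer orders to permute. The sum of the miR-506 family had rho -0.74 by all reads, 0.62 with TMM and DESeq2 factors, and 0.61 to 0.86 without 1 age. Other sums turned too. By all reads the blood cell markers had -0.98 and the endothelial and muscle markers -0.76. Without 1 age let-7 had -0.32 to 0.11 and the Sertoli or gonadal marker -0.54 to 0.21. That marker had 0.0476 with full-sequence matching. The 25 to 32 nt share with age had rho 0.829 over ages 10 to 90 (exact permutation p = 0.0583).

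The pachytene minus zygotene difference in that share was 7.70 points over distinct sequences, 44.5 over sequences with at least 2 reads and 39.1 for 26 to 32 nt. Scaled by all reads the family had 109 reads per 1000000 in rabbit at day 180, 32.3 in pig and 957 in rat, where 11 entries passed with 1 mismatch. tRNA fragments differed between mature sperm and round spermatids by 38.5 points of reads of 25 to 34 nt. Scaling by the spike-in was not run, as its sequence is not given in the sources used here. No paired analysis was possible because every group has 1 library. Depth limits the CRISPR and TALEN lines most, where a count of 3 is 15.2 and 11.5 per 1000000 miRNA reads, and among the mouse stages pachytene (8.07).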

Other observations

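The test of X-linked output and the counts of miR-465a-5p ends were chosen only after the results were seen.

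miR-465a-5p, the family member that rose most in the knockout lines, also differed from the control in its 3' ends. The 3' ends of other miRNAs were not counted, so a change of this member cannot be told apart from one across the libraries. Its 24-nt form TATTTAGAATGGCACTGATGTGAT made up 27.4% of its reads in control SSCs (95% interval 26.3% to 28.6%) and 22.5% in the other wild-type SSC library, but 63.4% in the TALEN and 62.6% in the CRISPR line. Its 23-nt form TATTTAGAATGGCACTGATGTGA went the other way, from 60.2% in the control to 29.2% and 29.3%. Per 1000000 miRNA reads the 23-nt form was higher in both lines too, at 7399 in the control, 25783 in the TALEN and 19527 in the CRISPR line. miR-465b-5p (0.09 and 0.15) and miR-465c-5p (0.27 and 0.30), which are near-identical, stayed within 2-fold.

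X-linked miRNAs outside the miR-506 family had a median at percentile 0.17 from zygotene to pachytene, and a hypothesis is lower output of the X chromosome in pachytene. The miR-506 family, X-linked too, lay at percentile 6.41, between the values set for and against this, so it cannot be told apart from other causes with these libraries. The feeder or stromal markers moved with this X-linked list: all 11 were lower at the same step (percentile 0.03), and both lists lay high from leptotene to zygotene (percentile 99.5 for the X-linked list and 98.5 for the markers) and from round spermatid to mature sperm (99.4 and 99.94). A change in RNA of other cells is therefore not separated from X chromosome output. This test replaced the percentile of the other X-linked list itself, which had been computed and restated the pattern.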
